A study of Mus musculus with 16 samples.

How the data were processed

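RNA of mouse stem cell derived macrophages was hybridised to 16 Agilent 4x44K arrays, 4 biological replicates in each of 4 groups, on 4 slides that each hold 1 array of every group. Per the labels, red (Cy5) is the sample and green (Cy3) an untreated reference RNA, and the control arrays carry untreated RNA in both colours to offset dye bias. The deposited LogRatio values are log10 of red over green on each spot, background-subtracted and corrected by linear and lowess dye normalisation in Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited median and processed signals are intensity values of each spot in both colours, per the file headers. Per the submitters' processing notes, the authors entered these log10 ratios into an analysis of variance in JMP Genomics without further normalisation and filtered at 2-fold. The deposited table of log10 values equals the LogRatio columns on every array (largest difference 0, and a median of 0 in each column), so it gives no separate alternative.

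The arrays hold 44397 spots, 43020 of them not controls, for 39429 probes. Spots of 1 probe were averaged (399 probes have 10 spots each). Control spots and outlier spots were left out, the latter between 188 and 690 per array. Probes were named through their accession and a table of mouse genes of assembly GRCm38.p6, whose build differs from that of the array design, so that no coordinates are given. This named 27234 probes with 20659 symbols, none with several symbols, and left 12195 probes unnamed here. Probes well above background in red on all 4 arrays of at least 1 group were kept (21458), and the probe with the highest mean log2 signal stood for its gene, which left 12759 genes. Of 3304 genes with several such probes, 11 had opposite calls after LPS and 0 after heme-albumin, and 623 had called and uncalled probes after LPS.

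Log10 ratios were multiplied to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group, all 16 arrays sharing 1 estimate of the spread, no block), with data.table version 1.17.8 for reading and matplotlib 3.10.9 for plots. P-values were adjusted by the Benjamini-Hochberg method over genes within each of 6 comparisons, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The moderated tests had a median of 14.1 degrees of freedom, the residual ones together with those that eBayes adds. The control arrays hold the same kind of RNA in both channels, so their spread can be mainly technical. The 30 gene lists, written before the data were examined like all planned choices, were tested with camera (preset correlation 0.01) on the moderated statistics where at least 5 members were measured, which was so for 28, and adjusted over 168 list tests. Camera asks whether a list ranks above or below the other genes, and fry, run beside it, whether its genes move one way on balance without comparing them to others. The lists cover inflammatory cytokines and mediators, chemokines, NF-kB pathway and feedback genes, interferon-stimulated genes, NRF2 targets, heme and iron handling, heat shock proteins, proteasome subunits, the integrated stress response, endoplasmic reticulum chaperones, cholesterol biosynthesis, LXR targets, cell cycle, alternative activation, antigen presentation, glycolysis and hypoxia, lysosome and autophagy, p53 targets, inflammasome and cell death, macrophage identity, housekeeping, and markers of embryonic stem cells, hematopoietic progenitors, neutrophils, mast cells, dendritic cells, lymphocytes, erythroid cells, fibroblasts and endothelium.

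Genes are named by a fixed rule: a set of genes chosen in advance, the 8 largest increases and 5 largest decreases against the control and the 5 largest each way between treatments among called genes whose 4 and 4 ratios do not overlap, and up to 4 members of each list, called ones first. Some genes that the rule names are not reported here. On simulated data of 12759 genes, with 200 changed singly and 2 lists shifted, the same code called 100 percent of genes changed 3-fold in the LPS comparison, 97.5 percent at 200 µM and 95 percent at 50 µM, but 57.5, 55 and 47.5 percent of those changed exactly 2-fold, and called 1, 1 and 0 of 12492 unchanged genes. It found both shifted lists and 0 others of 28. The simulated genes varied independently, so this does not test lists whose members move together.

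The slide carries all arrays of 1 replicate letter, so slide and replicate are the same block. Replicates a and b were scanned on the first scan day and c and d on the second, each with all groups, so values are also given with scan day as a block and within each day. Position on the slide is the same for all arrays of a group and cannot be told apart from it. Arrays of the same letter deviated together in 5 of the 6 comparisons, every correlation above 0.1 (from 0.102 between 200 µM and LPS to 0.502 between the doses). Between LPS and control they ran from 0.0966 to 0.113, so by a threshold of 0.1 the letters were not taken as pairs there. That threshold does not settle the pairing. Each LPS array still correlated best with the control array of its own letter (highest other letter 0.0552 to 0.0942). Replicate c between 200 µM and control did not (0.168 against 0.194), nor did replicate b between 200 µM and LPS (0.102 against 0.11). The sample titles give each letter the same tag in every group, but no label says what it marks. The alternatives chosen before the data were examined were normexp background correction (offset 50) with loess, no background subtraction with loess, the red channel alone with quantile normalisation, centring on the median, log ratios against 0 without the control arrays, no filter, a strict filter (above background in both channels on all arrays), every probe singly, outlier spots kept, 2 groups alone, replicate and scan day blocks, unmoderated analysis of variance, array weights, adjusted p alone, treat against 1.5-fold, camera with an estimated correlation, fry, and each replicate or array left out. Each scan day alone was chosen after seeing the data. The files hold median and not mean signals, so the first 2 alternatives use medians.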

Results

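Messenger RNA was measured on 16 microarrays from mouse macrophages grown from stem cells. The arrays fall into 4 groups of 4 replicates, lettered a to d, and the sample titles give each letter the same tag in every group. Untreated control cells stood at 0 h, and the other groups had been incubated for 8 h with heme-albumin at 50 µM, heme-albumin at 200 µM, or lipopolysaccharide (LPS) at 10 ng/mL. Heme is the iron-containing group of hemoglobin, here given to the cells bound to albumin, and LPS is a component of bacterial walls that activates macrophages through Toll-like receptor 4. The series asks whether heme acts as a trigger of inflammation, and LPS shows what a full inflammatory response of these cells looks like. Each array compared its sample, labelled red, with untreated reference RNA, labelled green. Between 49.9 and 59.4 percent of the 39429 probes were well above background in red, no spot was saturated, and 4 arrays per group limit the precision. The quality check of Agilent Feature Extraction marked control replicates a, c and d for evaluation. It also marked replicate d at 50 µM and replicates a and d at 200 µM and after LPS. The other arrays were marked as in range. Values below are differences of group means of the log2 ratio, with the standard error of the limma fit, and a gene is called when its adjusted p is under 0.05 and its change at least 2-fold.

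LPS against untreated control asks what these macrophages do when a known inflammatory trigger is given. Interleukin-1 beta, the cytokine released by inflammasome activation, rose by 6.74 ± 0.11 (adjusted p = 9.9e-16) and tumor necrosis factor (Tnf) by 4.16 ± 0.136 (adjusted p = 9.5e-13). Nos2, which makes the antimicrobial gas nitric oxide, rose by 5.09 ± 0.167 (adjusted p = 9.5e-13), and the chemokine Cxcl10, which attracts T cells, by 8.72 ± 0.205 (adjusted p = 2.8e-14). Some genes were not well above background on any control array, so only a bound can be given: Il6, the cytokine of the acute phase response, was at least 1660-fold higher (adjusted p = 1.6e-10), the prostaglandin synthase Ptgs2 at least 869-fold (adjusted p = 4e-14), and the interferon gene Ifnb1 at least 32.7-fold (adjusted p = 3e-08). Such a bound sets the bright group's mean red signal against the dim group's, each dim array taken at the higher of its own signal and the lowest signal well above background. Genes of cell division fell, among them the spindle gene Aspm by 6.29 ± 0.174 (adjusted p = 1.6e-13) and the mitotic activator Cdc20, which fell by 4.11 ± 0.0622 (adjusted p = 4.7e-16). The signalling adaptor Zfyve28 fell by 6.69 ± 0.123 (adjusted p = 2.8e-15) on the brightest of its 3 probes, and its smallest change was −2.35. The chemokine Ccl2 rose by 4.56 ± 0.458, the interferon-induced Ifit1 by 5.48 ± 0.167 and the arginine-degrading enzyme Arg1 by 3.6 ± 0.353.

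LPS also moved genes that handle heme and iron. Spic, the transcription factor of iron-recycling macrophages, rose by 5.66 ± 0.209 (adjusted p = 3.3e-12), and Hmox1, the heme-degrading enzyme, by 2.65 ± 0.184 (adjusted p = 2.4e-08). Slc40a1, the iron exporter ferroportin, fell by 2.36 ± 0.28 (adjusted p = 3e-06). The glutathione gene Gclm (0.345 ± 0.185), the sulfiredoxin gene Srxn1 (0.58 ± 0.194) and the quinone reductase Nqo1 (−0.854 ± 0.207) were not called over both scan days. Their changes on the first and second scan day alone were 0.759 and −0.0694 for Gclm, 1.09 (called) and 0.0718 for Srxn1, and −0.649 and −1.06 (called) for Nqo1, whereas the heat shock gene Hspa1a rose by 3.92 ± 0.0857. The cystine transporter gene Slc7a11 had log2 ratios of 9.16, 8.5, 5.79 and 7.31 on LPS replicates a to d, against 0.354 to 1.02 in the control. It was dim on most control arrays, so no size of change is given.

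Of 12759 genes, 3924 were called after LPS (30.8 percent), 1787 higher and 2137 lower, of which 376 and 190 changed at least 8-fold. The count was 3928 with scan day as a block, 3659 on the first scan day alone and 4307 on the second. The direction of the majority depends on the scaling, with 1507 higher and 1393 lower under normexp, 1558 and 1410 without background subtraction, 1965 and 1888 with arrays centred on their median, and 1655 and 2318 from the red channel alone. In the inflammatory cytokine and mediator list 24 of 24 measured members were called higher (median 4.33, camera adjusted p = 7.6e-29). Of the interferon-stimulated genes 41 of 42 were higher (median 2.96, adjusted p = 1.3e-51), among them Rsad2 at 5.66. In the NF-kB pathway and feedback list 29 of 30 rose (median 2.85, adjusted p = 1.8e-28), for example Tnip1 by 3.11 and Nfkb2 by 2.6. Of the chemokines 18 of 20 rose (median 4.93, or 4.61 with dim genes at their bounds, adjusted p = 7.9e-10). Antigen presentation genes rose, 14 of 24 with 1 lower (median 1.3, adjusted p = 2.9e-09), with the peptide transporter gene Tap1 at 2.77. So did 11 of 21 inflammasome and cell death genes (median 1.23, adjusted p = 0.00048), with Casp1 at 2.98, while 2 fell. The list medians on the 2 scan days were 4.44 and 4.56, 2.88 and 3.14, 3.04 and 3.16, 4.65 and 4.68, 1.28 and 1.21, and 0.913 and 1.22 in that order. The MHC class II gene H2-Ab1 rose by 1.3 ± 0.166, with 0.878 on the second scan day, under 2-fold. These 6 lists kept their calls with an estimated correlation between member genes.

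Another 5 lists were called after LPS, and these did not keep their calls with an estimated correlation. Cell cycle genes fell, 30 of 35 with 1 higher (median −2.29, adjusted p = 9.6e-15, adjusted p = 0.19 with an estimated correlation, and −2.77 and −2.12 on the scan days). Glycolysis and hypoxia genes rose, 13 of 28 (median 0.917, adjusted p = 0.00017, adjusted p = 0.28 with an estimated correlation, 1.11 and 0.811 on the scan days), for example the glucose transporter gene Slc2a1 by 2.93. Integrated stress response genes rose, 13 of 27 with 1 lower (median 0.898, adjusted p = 0.03, adjusted p = 0.24 with an estimated correlation, 1.08 and 0.755 on the scan days), with Atf3 at 1.5. Heat shock genes rose, 11 of 28 (median 0.718, adjusted p = 0.00032, adjusted p = 0.16 with an estimated correlation, 1.06 and 0.504 on the scan days). So did 7 of 32 proteasome subunits (median 0.618, adjusted p = 2.7e-05, adjusted p = 0.41 with an estimated correlation, 0.794 and 0.46 on the scan days). With scan day as a block the 11 called lists stayed 11.

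The other lists were not called after LPS by camera. Of 36 NRF2 targets 8 rose and 1 fell (median 0.287, adjusted p = 0.32), and of 34 heme and iron handling genes 9 rose and 8 fell (median 0.0139, adjusted p = 0.42). Cholesterol biosynthesis genes fell in 4 of 24 cases with 0 higher (median −0.522, adjusted p = 0.23), for example Dhcr7, which fell by 2.03, and LXR targets in 4 of 13 with 1 higher (median −0.704, adjusted p = 0.37), for example Apoe by 2.11. Further medians were 0.317 for endoplasmic reticulum chaperones (adjusted p = 0.25), −0.21 for lysosome and autophagy genes (adjusted p = 0.71) and −0.0332 for p53 targets (adjusted p = 0.89). The alternative activation list had a median of −0.179 but a positive mean and test direction (mean 0.0892, adjusted p = 0.87), and macrophage identity genes a median of −0.127 with a positive test direction (adjusted p = 0.38). The housekeeping list was not called (median 0.087, adjusted p = 0.82). Its member Actb was called higher by 1.73, but from the red channel alone it was at −0.336. Marker lists of other cell types stayed uncalled, with medians of 0.183 for embryonic stem cell (0 of 7 higher and 1 lower, adjusted p = 0.92, test direction negative), 0.244 for hematopoietic progenitor (3 of 8 and 2, adjusted p = 0.68), 1.07 for neutrophil (3 of 6 and 0, adjusted p = 0.64) and 0.0855 for dendritic cell (2 of 8 and 2, adjusted p = 0.56). The others were at 0.559 for erythroid and megakaryocyte (2 of 6 and 0, adjusted p = 0.44), 1.74 for fibroblast and stromal (3 of 6 and 0, adjusted p = 0.39) and 1.34 for endothelial markers (4 of 7 and 1, adjusted p = 0.39). Mast cell and lymphocyte markers, with 4 measured members each, were not tested as lists.

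Heme-albumin at 200 µM against untreated control asks what heme does at the higher dose. Among genes that recycle heme iron, Spic rose by 5.78 ± 0.209 (adjusted p = 4.7e-10), the iron exporter Slc40a1 by 4.19 ± 0.302 (adjusted p = 3.8e-07) and Hmox1 by 3.7 ± 0.17 (adjusted p = 1.4e-08). Tfrc, the receptor that takes up iron-loaded transferrin, fell by 4.06 ± 0.101 (adjusted p = 7.2e-12), with −2.37 on its other probe. Antioxidant genes rose, among them Gclm, which makes glutathione, by 2.38 ± 0.185 (adjusted p = 4e-07), the sulfiredoxin gene Srxn1 by 1.87 ± 0.194 (adjusted p = 6.6e-06) and Nqo1 by 1.44 ± 0.207 (adjusted p = 0.00014). The cystine transporter gene Slc7a11 was called higher (adjusted p = 9.5e-05), but it was well above background on only 1 of 4 control arrays, so no size is given, and after normexp background correction it was not called (1.01). Outside these functions, Acod1, which makes itaconate, rose by 3.64 ± 0.18 (adjusted p = 1.1e-08), the solute carrier Slc22a23 by 4.64 ± 0.445 and the organic anion transporter Slco2b1 fell by 2.83 ± 0.144. Thbs1, which encodes the matrix protein thrombospondin, fell by 4.31 ± 0.442 (adjusted p = 5.9e-06).

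Inflammatory genes divided at this dose. Tnf rose by 2.11 ± 0.136 (adjusted p = 6e-08) and was higher than every control array on 4 of 4 arrays, whereas Il1b (−0.101 ± 0.11, adjusted p = 0.57) and Nos2 (0.0645 ± 0.167, adjusted p = 0.83) were not called. Cxcl10 was higher by 0.675 ± 0.205, under 2-fold (adjusted p = 0.028), and Ifnb1, above background on 2 of 4 heme arrays and no control array, was not called (adjusted p = 0.79). The neutrophil-attracting chemokine Cxcl1 rose by 2.72 ± 0.452 (adjusted p = 5e-04), but by 0.251 after normexp correction. Ptgs2 was above background on 2 of 4 heme arrays and no control array, and was called at a bound of at least 1.09-fold (adjusted p = 0.00032), but not after normexp correction (0.127). Il6 was called with a bound of at least 2.41-fold from 3 of 4 arrays (adjusted p = 0.015), and the call was lost without replicate c (fitted change 1.7) or without replicate d (2.12). The monocyte-attracting chemokine Ccl2 went the other way and fell by 1.58 ± 0.424 (adjusted p = 0.016), a call lost without replicate b (−1.42) and not made on the second scan day alone (−0.857). Ifit1 fell by 1.11 ± 0.167 (adjusted p = 0.00022) and lost its call without 1 of the heme arrays, replicate d (−0.996). Arg1 fell by 1.55 ± 0.353 (adjusted p = 0.0053), with 0 calls under 3 other corrections (−0.364 with normexp, −0.631 without background subtraction, −1.67 from the red channel alone). H2-Ab1 (0.0509 ± 0.166), Hspa1a (0.684 ± 0.0857), Dnajb1 (0.061 ± 0.071), Ddit3 (−0.341 ± 0.0746), Atf3 (0.105 ± 0.0965) and the ferritin gene Fth1 (0.462 ± 0.0732) were not called.

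**Figure D1:**
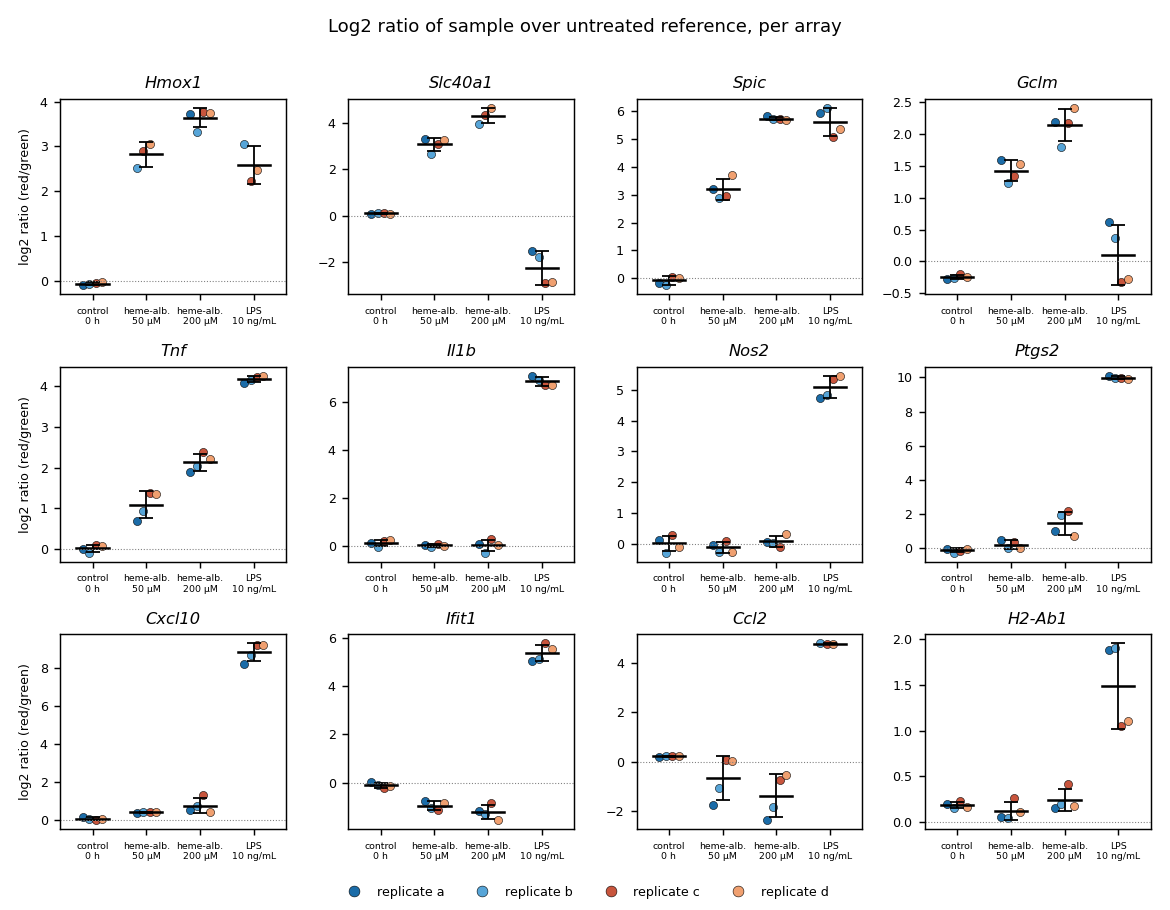
Log2 ratio of sample over reference for 12 genes on each array, by group. Dots are coloured by replicate (a and b from the first scan day, c and d from the second), with bars at the mean and error bars of 1 SD over 4 arrays, or 3 where an outlier spot was left out (Hmox1 at 50 µM and after LPS, Slc40a1 at 200 µM, Ccl2 after LPS). Il1b and Nos2 stand near 0 at both heme doses and near 7 and 5 after LPS, whereas Slc40a1 rises with heme and falls after LPS.

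At 200 µM, 383 genes were called (3 percent), 258 higher and 125 lower, and 20 and 2 of them changed at least 8-fold. The count fell to 151 under normexp and 228 without background subtraction, and it was 391 with scan day as a block, 370 on the first scan day alone and 429 on the second. NRF2 targets, the antioxidant genes switched on by electrophiles, had the largest median and the lowest adjusted p of the called lists, with 19 of 36 called higher and none lower (median 1.09, adjusted p = 9e-59, and 1.11 and 1.07 on the scan days). They included the thioredoxin reductase gene Txnrd1 at 1.98 and the malic enzyme gene Me1 at 1.77. Cholesterol biosynthesis genes rose, 9 of 24 (median 0.834, adjusted p = 1.7e-22, 0.722 and 0.902 on the scan days), for example the farnesyl diphosphate synthase gene Fdps by 1.11 ± 0.0683. LXR targets, some of which export cholesterol, fell, 4 of 13 (median −0.348, adjusted p = 0.00014, −0.227 and −0.468 on the scan days), for example Abca1 by 1.64 ± 0.187 and Apoe by 1.46 ± 0.132. Of 34 heme and iron handling genes 6 rose and 1 fell (median 0.0833, mean 0.461, adjusted p = 0.003, 0.0646 and 0.155 on the scan days). Integrated stress response genes moved up on balance, 3 of 27 called higher and 1 lower (median 0.412, adjusted p = 0.00021, 0.383 and 0.442 on the scan days).

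Among the immune lists at 200 µM, 9 of 30 NF-kB pathway and feedback genes were called higher and none lower (median 0.468, adjusted p = 4.6e-17, 0.528 and 0.477 on the scan days), for example the inhibitor genes Nfkbia by 1.36 ± 0.108 and Nfkbie by 1.35 ± 0.114. Of the 24 inflammatory cytokines and mediators 7 were called higher (median 0.216, or 0.16 with dim genes at their bounds, adjusted p = 0.00014, 0.0882 and 0.409 on the scan days). Interferon-stimulated genes moved down, 7 of 42 called lower and none higher (median −0.592, adjusted p = 3.7e-23, −0.547 and −0.626 on the scan days), for example Usp18 by −1.24 ± 0.113 and Rtp4 by −1.17 ± 0.0863. Chemokines went both ways, 4 of 20 higher and 2 lower (median 0.0208, adjusted p = 0.39). Macrophage identity genes moved down slightly, with 2 of 28 called lower (median −0.166, adjusted p = 5.9e-05, −0.125 and −0.182 on the scan days), and the Fc receptor gene Fcgr1 fell by 1.58 ± 0.0602. Proteasome subunits were higher by a median of 0.166 with 0 called genes (adjusted p = 2.9e-06, adjusted p = 0.32 with an estimated correlation, 0.179 and 0.182 on the scan days). The housekeeping list was called lower (median −0.0494, adjusted p = 0.0021), and its call ended after normexp correction (adjusted p = 0.73). It holds Tfrc, as the heme and iron handling list does, and was not tested without that gene. Fibroblast and stromal markers were called with 2 of 6 genes higher (median 0.307, or 0 with dim genes at their bounds, adjusted p = 0.047). The call ended with scan day as a block (adjusted p = 0.067), with an estimated correlation (adjusted p = 0.064) and without replicate b (adjusted p = 0.1) or d (adjusted p = 0.07). The other 10 of the 12 called lists kept their calls with an estimated correlation. No call was made for heat shock genes (median 0.0866, adjusted p = 0.13), endoplasmic reticulum chaperones (0.0436, adjusted p = 0.51), cell cycle (−0.132, adjusted p = 0.3), antigen presentation (−0.0448, adjusted p = 0.76) or inflammasome and cell death genes (0.2, adjusted p = 0.077, with adjusted p = 0.045 with scan day as a block).

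**Figure D2:**
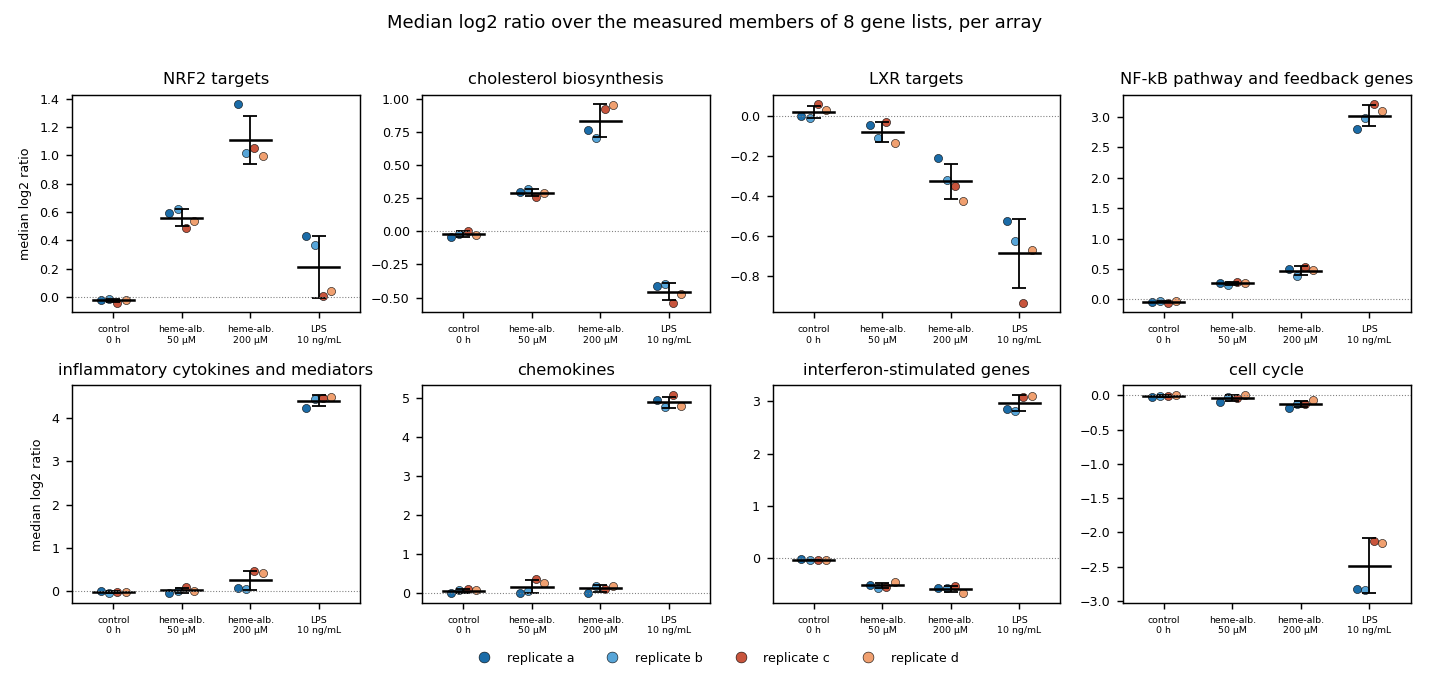
Median log2 ratio over the measured members of 8 gene lists on each array, by group, with dots coloured by replicate (a and b from the first scan day, c and d from the second) and bars at the mean. NRF2 targets stand between 0.998 and 1.36 at 200 µM, and interferon-stimulated genes between −0.531 and −0.676 there against 2.82 to 3.1 after LPS.

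Heme-albumin at 50 µM against untreated control asks what the lower dose does. The iron genes responded here too: Spic rose by 3.26 ± 0.209 (adjusted p = 1.1e-06), Slc40a1 by 2.96 ± 0.28 (adjusted p = 4.6e-05) and Hmox1 by 2.88 ± 0.184 (adjusted p = 4.4e-06), and Tfrc fell by 3.32 ± 0.101 (adjusted p = 1.2e-10). The other probe of Tfrc was at −1.47 and not called. Gclm rose by 1.67 ± 0.185 (adjusted p = 0.00011) and Acod1 by 1.94 ± 0.18 (adjusted p = 4.3e-05), both without a call from the red channel alone (1.61 and 2.07). Tnf rose by 1.07 ± 0.136 (adjusted p = 0.00034), close to the 2-fold threshold, and lost its call without replicate c (0.994) or without the heme arrays of replicates c or d (0.971 and 0.986), and on the first scan day alone (0.862). Il1b (−0.0992 ± 0.11), Nos2 (−0.127 ± 0.167), Cxcl10 (0.334 ± 0.205), Ccl2 (−0.887 ± 0.424), Nqo1 (0.548 ± 0.207) and Srxn1 (0.687 ± 0.194) were not called. Il6, above background on 2 of 4 heme arrays and no control array, was not called (adjusted p = 0.34). Its log2 ratios were 0.143 and 0.392 on replicates a and b and 2.56 and 2.31 on c and d, and it was called on the second scan day alone (adjusted p = 0.045). Cxcl1 was not called either (1.47 ± 0.452, adjusted p = 0.11), but was with scan day as a block (adjusted p = 0.00093) or the replicate as a block (adjusted p = 0.0032).

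At 50 µM, 47 genes were called (0.368 percent), 37 higher and 10 lower. The count was 19 under normexp, 28 without background subtraction and 95 for log ratios against 0. It was 56 with scan day as a block, 53 on the first scan day alone and 46 on the second. NRF2 targets shifted up, with 6 of 36 called (median 0.554, adjusted p = 3.2e-62, 0.644 and 0.49 on the scan days). So did cholesterol biosynthesis genes, with 1 of 24 called (median 0.291, adjusted p = 7.1e-13, 0.317 and 0.229 on the scan days). NF-kB pathway genes were higher by a median of 0.303 with 0 of 30 called (adjusted p = 2.9e-20, 0.275 and 0.334 on the scan days). Interferon-stimulated genes were lower by a median of −0.475 with 0 of 42 called (adjusted p = 3.2e-63, −0.497 and −0.455 on the scan days). In these lists limma gave an adjusted p under 0.05 for 12 and 31 genes in those directions. Heme and iron handling genes were called higher (4 of 34 higher, 1 lower, median 0.0704, adjusted p = 0.0032, 0.0635 and 0.0709 on the scan days). The housekeeping list, again tested with Tfrc in it, was lower (median −0.0391, adjusted p = 1.2e-05), a call that ended after normexp correction (adjusted p = 0.49). These 6 lists kept their calls with an estimated correlation. The inflammatory list did not (2 of 24 higher, median 0.0841, or 0 with dim genes at their bounds, adjusted p = 0.0055, adjusted p = 0.16 with an estimated correlation, −0.00136 and 0.119 on the scan days). Nor did proteasome subunits (median 0.0325, adjusted p = 0.011, adjusted p = 0.66 with an estimated correlation) or inflammasome and cell death genes (median 0.0961, adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation), whose call also ended without replicate c (median 0.0814, adjusted p = 0.058). With scan day as a block the 9 called lists stayed 9, and LXR targets (median −0.148, adjusted p = 0.39) and chemokines (0.12, adjusted p = 0.39) were not called.

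All comparisons with the control share a limit: the control cells were taken at 0 h and the treated cells at 8 h, and no cells received albumin without heme. Changes against the control can therefore include those of 8 h in culture or of albumin, whereas treatments compared with each other share the 8 h.

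Heme-albumin at 200 µM against 50 µM asks how the response grows with the dose. At the higher dose the cholesterol export gene Abca1 was lower by 1.31 ± 0.187, written as −1.31 (adjusted p = 0.00044), and Apoe by 1.14 ± 0.132, written as −1.14 (adjusted p = 7.7e-05), neither of them called at 50 µM (−0.328 and −0.318). Thbs1 fell by 2.53 ± 0.442 (adjusted p = 0.0023). Spic was higher by 2.52 ± 0.209 (adjusted p = 4.1e-06), the lectin receptor gene Clec10a by 1.7 ± 0.143 (adjusted p = 4.5e-06) and the glutathione reductase gene Gsr by 1.13 ± 0.178. Hmox1 differed by 0.816 ± 0.184, under 2-fold (adjusted p = 0.017), and Slc40a1 by 1.23 (adjusted p = 0.023), a call lost without replicate b (adjusted p = 0.097), c (adjusted p = 0.14) or d (adjusted p = 0.15). Tnf was higher by 1.04 (adjusted p = 0.00021), a call lost without replicate a (0.986), without single heme arrays (0.91 without replicate a and 0.991 without replicate b at 50 µM, 0.954 without replicate c at 200 µM) and after normexp correction (0.46). Of 12759 genes 104 were called, 79 higher and 25 lower at the higher dose. The count fell to 31 under normexp and 68 under a strict filter, and it was 120 with scan day as a block, 105 on the first scan day alone and 129 on the second. All 47 genes called at 50 µM were called in the same direction at 200 µM, and 46 of them changed more there. Both doses share the control arrays, which can add to this overlap, by an amount that was not tested.

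NRF2 targets were higher at the higher dose (5 of 36 called, median 0.496, adjusted p = 1.4e-30, 0.513 and 0.49 on the scan days). So were cholesterol biosynthesis genes (1 of 24 called, median 0.529, adjusted p = 5.2e-21, 0.394 and 0.646), NF-kB pathway genes (1 of 30, median 0.152, adjusted p = 2.7e-08, 0.128 and 0.23) and inflammatory cytokines and mediators (4 of 24, median 0.136, adjusted p = 0.00027, 0.0967 and 0.246). Higher medians were also called for integrated stress response genes (1 of 27, median 0.294, adjusted p = 1.8e-06, 0.26 and 0.407) and p53 targets (0 of 18, median 0.0944, adjusted p = 0.0075, 0.155 and 0.0493). LXR targets were lower (3 of 13 called, median −0.387, adjusted p = 1.4e-07, −0.331 and −0.422), and macrophage identity genes as well (0 of 28, median −0.104, adjusted p = 3.5e-07, −0.119 and −0.164). These 8 lists kept their calls with an estimated correlation. The p53 call was not made on the second scan day alone (adjusted p = 0.23). Proteasome subunits lost their call with an estimated correlation (median 0.151, adjusted p = 1.6e-07, adjusted p = 0.25 with an estimated correlation). Heme and iron handling genes lost it too (median 0.0502, adjusted p = 0.034, adjusted p = 0.11 with an estimated correlation), and also without replicate a (adjusted p = 0.074), without replicate a or d at 200 µM (adjusted p = 0.072 and 0.076) and without replicate c at 50 µM (adjusted p = 0.067). The heat shock call (median 0.0973, adjusted p = 0.016, adjusted p = 0.41 with an estimated correlation) ended without replicate d at 200 µM (adjusted p = 0.055). The lysosome and autophagy call (median −0.102, adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation) ended without replicate c (adjusted p = 0.085) or d (adjusted p = 0.054) and on the first scan day alone (adjusted p = 0.48). Interferon-stimulated genes did not differ detectably between the doses (median −0.0989, adjusted p = 0.09), although they were called lower without replicate b (median −0.103, adjusted p = 0.042) or c (median −0.14, adjusted p = 0.00018).

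**Figure D3:**
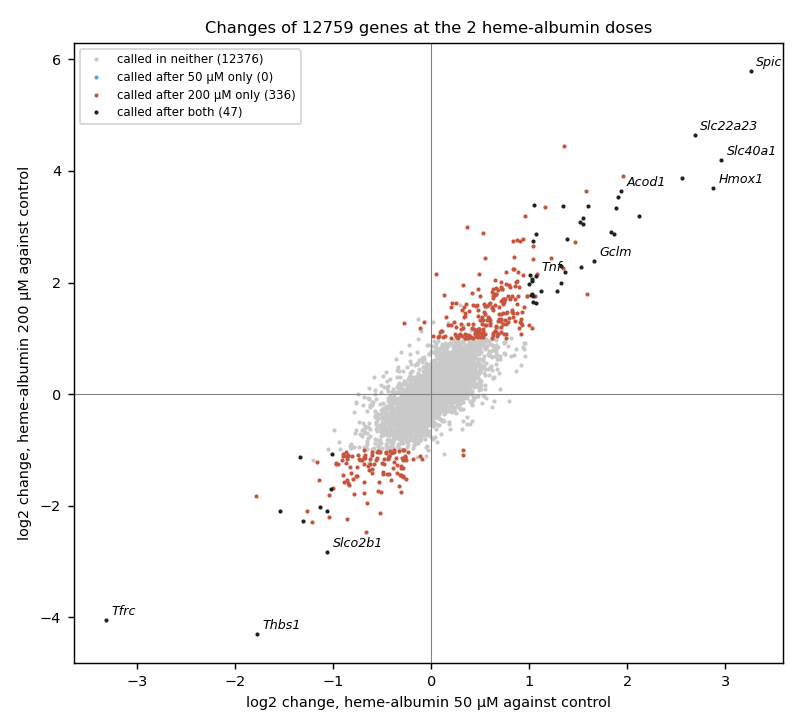
Log2 change against the control at 50 µM (x axis) and at 200 µM (y axis) heme-albumin for the 12759 genes tested, coloured by the doses at which each was called (neither 12376, 200 µM only 336, both 47). Of the 47 genes called at both doses 46 changed more at 200 µM, and 0 genes were called at 50 µM only.

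Heme-albumin at 200 µM against LPS compares the treatments at the same time. Il1b was lower by 6.84 ± 0.11 after heme, written as −6.84 (adjusted p = 7.6e-16), Nos2 stood at −5.03 ± 0.167, Cxcl10 at −8.05 ± 0.205 and Tnf at −2.05 ± 0.136 (adjusted p = 2.9e-09). Ifit1 (−6.59 ± 0.167) was lower too, and so were Ptgs2 and Il6, for which no size is given because they were above background on only 2 and 3 of the 4 heme arrays. Slc40a1 was higher after heme by 6.55 ± 0.302, Nqo1 by 2.3 ± 0.207 and Gclm by 2.04 ± 0.185, and Zfyve28, which LPS lowered, by 6.61 ± 0.123, or 2.16 on another of its 3 probes. Spic did not differ (0.121 ± 0.209), although after normexp correction it was lower after heme (−1.08), and Slc7a11 was lower after heme (−2.55 ± 0.611). Of 12759 genes 3872 were called, 2141 higher and 1731 lower after heme, with 3877 when scan day was a block and 3657 and 4271 on the scan days alone. The majority turned with other corrections, to 1341 higher and 1493 lower under normexp and 1435 and 1493 without background subtraction.

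The lists lower after 200 µM heme than after LPS included the interferon-stimulated genes (0 higher and 41 of 42 lower after heme, median −3.51, adjusted p = 6.2e-75), the inflammatory cytokines and mediators (24 of 24 lower, median −3.52, adjusted p = 4.8e-25), NF-kB pathway genes (28 of 30 lower, median −2.43, adjusted p = 2.4e-19) and chemokines (18 of 20 lower, median −4.73, adjusted p = 2e-09). Antigen presentation (13 of 24 lower, 1 higher, median −1.23, adjusted p = 5.8e-10) and inflammasome and cell death genes (10 of 21 lower, 3 higher, median −0.648, adjusted p = 0.0029) were lower as well. Their medians on the 2 scan days were −3.34 and −3.7, −3.85 and −3.31, −2.14 and −2.49, −4.64 and −4.55, −1.23 and −1.12, and −0.691 and −1.09. These 6 calls, and no others, were kept with an estimated correlation. Cell cycle genes (29 of 35 higher, median 2.2, adjusted p = 3.7e-14, adjusted p = 0.2 with an estimated correlation), cholesterol biosynthesis genes (13 of 24 higher, median 1.04, adjusted p = 5.6e-05, adjusted p = 0.16 with an estimated correlation) and NRF2 targets (15 of 36 higher and 1 lower, median 0.865, adjusted p = 0.007, adjusted p = 0.64 with an estimated correlation) were higher after heme. Glycolysis and hypoxia genes (−1.05, adjusted p = 5.6e-05, adjusted p = 0.23 with an estimated correlation), heat shock genes (−0.54, adjusted p = 0.0016, adjusted p = 0.24 with an estimated correlation), proteasome subunits (−0.318, adjusted p = 0.0032, adjusted p = 0.64 with an estimated correlation) and macrophage identity genes (−0.433, adjusted p = 0.035, adjusted p = 0.29 with an estimated correlation) had lower medians. The macrophage identity call ended without replicate b (adjusted p = 0.073) or c (adjusted p = 0.051) and on each scan day alone (adjusted p = 0.065 and 0.21), and the heat shock and proteasome calls on the second scan day alone (adjusted p = 0.078 and 0.065).

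Heme-albumin at 50 µM against LPS gave a like picture. Il1b (−6.84 ± 0.11, adjusted p = 6.4e-16), Nos2 (−5.22 ± 0.167), Cxcl10 (−8.39 ± 0.205) and Tnf (−3.09 ± 0.136) were lower after heme, and Slc40a1 was higher (5.32 ± 0.28). Spic was lower by 2.4 ± 0.209, written as −2.4, and Hmox1 did not differ detectably (0.233). Of 12759 genes 3912 were called, 2135 higher and 1777 lower after heme, with 3919 when scan day was a block and 3640 and 4285 on the scan days alone. Here too the majority turned, to 1347 higher and 1509 lower under normexp and 1424 and 1519 without background subtraction. The 6 immune lists lower at 200 µM were lower here too, with medians of −3.53 (interferon-stimulated, adjusted p = 2.6e-69), −4.26 (inflammatory, adjusted p = 4e-27), −2.67 (NF-kB, adjusted p = 1.1e-22), −5.23 (chemokines, adjusted p = 2.2e-09), −1.28 (antigen presentation, adjusted p = 7.2e-10) and −0.852 (inflammasome, adjusted p = 0.0018). They kept their calls with an estimated correlation. Cell cycle (2.34, adjusted p = 1.7e-14, adjusted p = 0.19 with an estimated correlation) and cholesterol biosynthesis genes (0.76, adjusted p = 0.022, adjusted p = 0.53 with an estimated correlation) were higher. Lower medians were called for glycolysis and hypoxia (−1.17, adjusted p = 6.5e-05), heat shock (−0.68, adjusted p = 0.00036) and proteasome (−0.51, adjusted p = 0.00014), with adjusted p = 0.24, 0.16 and 0.49 with an estimated correlation. The integrated stress response was lower too (−0.962, adjusted p = 0.0499, adjusted p = 0.3 with an estimated correlation). Its call ended without replicate d (adjusted p = 0.055) or single arrays of the control (replicate c, adjusted p = 0.053) and of heme at 50 µM (replicate c, adjusted p = 0.064, and d, adjusted p = 0.061) and 200 µM (replicate d, adjusted p = 0.056).

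Across genes, which are not independent replicates, the changes after 200 µM heme and after LPS correlated weakly (Pearson r 0.22, Spearman rho 0.179, 12759 genes). Within each replicate letter r lay between 0.196 and 0.26. Unchanged groups simulated against the same controls gave r 0.501, because their changes hold only each group's own error and the shared control error. The covariance is therefore the comparable quantity. It was 0.119 against a simulated 0.0124, a difference of 0.107. With the 4 controls split between the comparisons, r lay between 0.195 and 0.211. At 50 µM r was 0.102, rho 0.107, the covariance 0.0299 and its difference from the simulated one 0.0175, and split controls gave 0.0585 to 0.0871. Scan day as a block left r at 0.22 and 0.102, and the scan days alone gave 0.21 and 0.227 at 200 µM, and 0.0812 and 0.138 at 50 µM. Of the 258 genes called higher at 200 µM, LPS raised 126 (36.1 for independent lists), lowered 20 (43.2) and left 112 uncalled. Of the 125 genes called lower, LPS lowered 56 (20.9 for independent lists), raised 38 (17.5) and left 31 uncalled. Of the 37 and 10 genes called higher and lower at 50 µM, LPS raised 15 and lowered 1 in the same direction (5.18 and 1.67 for independent lists), and 5 and 3 went opposite ways (6.2 and 1.4). Simulated unchanged groups shared 0 called genes, as limma called none in them. The independent overlap leaves out the shared controls and the simulation leaves out the effects.

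Over the 6 comparisons, the numbers of called genes adjusted over the list alone were the same as those over all genes in all but 3 cases: chemokines at 50 µM (2 against 0) and at 200 against 50 µM (3 against 1), and erythroid markers at 200 µM against LPS (1 against 2). Some genes count under 2 lists: Hmox1, Blvrb, Fth1 and Ftl1 under NRF2 targets and heme and iron handling, and Sqstm1 under NRF2 targets and lysosome and autophagy. So do Vegfa and Ero1a under integrated stress response and glycolysis and hypoxia, Tfrc, Gapdh and Pgk1 under housekeeping and another list, Ctss under antigen presentation and macrophage identity, and Ccl24 under chemokines and alternative activation. Interleukin-12 subunit Il12b has no named probe here and was not analysed.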

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

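The tests of a weaker copy of the LPS response, of 8 h of incubation and of albumin, and those of compressed ratios and of a shift of like size on all treated arrays, were chosen only after the results were seen.

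Inflammatory and interferon-stimulated genes went apart in the cells given heme-albumin: at 200 µM, 18 of the 24 inflammatory cytokines and mediators and 28 of the 30 NF-kB genes had a log2 change above 0, while only 3 of the 42 interferon-stimulated genes did. A proportional, weaker copy of the LPS response is argued against only for the changes against the 0 h control. There the 41 interferon-stimulated genes that LPS raised had a median change of −0.595 at 200 µM (−0.56, −0.558, −0.474 and −0.74 on replicates a to d, SD 0.112), and Il1b, at 6.74 after LPS, stood at −0.101. These values cannot exclude a weak rise hidden by a fall over 8 h in culture, which stays open below. They also leave open that part of the LPS pathways is shared. Incubation for 8 h as the whole cause is argued against too, since both doses share it and the members of the 2 lists were higher at 200 than at 50 µM by a median of 0.152 (0.104, 0.179, 0.288 and 0.173 on replicates a to d, SD 0.0759). Albumin given with the heme cannot be told apart from the heme, because 0 arrays hold cells with albumin alone, so a direct effect of heme on these genes stays a hypothesis.

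Interferon-stimulated genes were lower at both doses, with list medians of −0.475 at 50 µM and −0.592 at 200 µM. Background correction or normalisation as the cause is argued against, since over 4 other corrections and normalisations the weakest median at 200 µM was −0.456. Incubation for 8 h stays open: from 50 to 200 µM the median moved by −0.0989 (−0.119, −0.0539, 0.0936 and −0.272 on replicates a to d, SD 0.152), with no call over all arrays. Yet 32 of the 42 members were lower at 200 than at 50 µM and 10 higher, and the list was called lower when replicate b or c was left out. The doses therefore do not decide whether the fall came from time in culture. The untreated cells at 0 h may have stood higher, and a biological effect of heme or albumin is open as well.

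The response to LPS differed between the scan days by a test of the difference itself, in which limma called 574 of 12759 genes, 334 larger or less negative and 240 smaller on the second, 147 of them with opposite signs, for example Egr1 (−0.0921 and 2.65) and Zfp618 (−1.41 and 1.82), while Cxcl5 (8.18 and 4.7) and Csf2 (5.53 and 2.6) were higher on both days, all 4 chosen after their values were seen. Ratios compressed on 1 day are argued against as the whole cause, since the ratio of spreads of the 2 days was 1.05. Compression does not turn signs, but the 147 genes were counted by sign alone, without testing each day's change against 0. Changes near 0 on 1 day, as for Egr1, count among them, so the 147 decide little here. After the first day's changes were scaled by that ratio, 509 of the 574 stayed called in the same direction. So small a scaling could end few calls, so this count adds little. A shift of like size on all treated arrays is argued against as the whole cause. At 200 µM the 574 genes differed in the direction of LPS by a median of only 0.102 (spread over genes 0.288). They were picked for their difference after LPS, so their median of 1.24 there can be inflated and part of the gap is built in. Over all genes, limma called 0 at 200 µM (1 at adjusted p alone, 1510 at an unadjusted p under 0.05, against 5580 for LPS) and 0 at 50 µM (0 and 728). Background correction may play a part: under normexp 282 of the 574 stayed called (49.1 percent), although 567 kept their direction and 489 also an adjusted p under 0.05, so most calls ended as the median size of the difference went from 1.24 to 0.996, below the 2-fold threshold. Without background subtraction 298 stayed called (51.9 percent), and from the red channel alone 427 (74.4 percent). A smaller shift that the heme arrays share stays open, with 7 lists differing at each dose, and scan day coincides with the pair of replicates a and b against c and d, so the cultures and the scans cannot be told apart, and no biological explanation was tested, since the design names none.

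Lists differed between the scan days in 7 cases for LPS, 7 for 200 µM and 7 for 50 µM. These tests used the preset correlation of 0.01 alone and were not repeated with an estimated one, with which the cell cycle list lost its call after LPS. For LPS the clearest was the cell cycle, with medians of −2.77 and −2.12 (adjusted p = 2.7e-20), followed by interferon-stimulated genes, NRF2 targets (0.452 and 0.0375, adjusted p = 0.0074), NF-kB, heat shock, proteasome and glycolysis genes. At 200 µM cholesterol biosynthesis genes were at 0.722 and 0.902 (adjusted p = 7.9e-06) and inflammatory genes at 0.0882 and 0.409 (adjusted p = 0.0071), beside chemokines, NF-kB, endoplasmic reticulum chaperones, LXR targets and glycolysis. At 50 µM the 7 were inflammatory genes, chemokines (0.0405 and 0.274), NRF2 targets (0.644 and 0.49), the integrated stress response, endoplasmic reticulum chaperones, LXR targets and endothelial markers.

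Some single arrays stood apart from the other 3 of their group. At 200 µM Hmox1 was 3.32 on replicate b against 3.73 to 3.76, Spic 5.79 on replicate a against 5.68 to 5.69, and H2-Ab1 0.421 on replicate c against 0.158 to 0.2. The share of probes above background in green was 56.3 percent on LPS replicate b against 51.2 to 52.1. Among the named genes, 22 of 277 had such an array in the control group, 7 of 273 at 50 µM, 14 of 273 at 200 µM and 10 of 260 after LPS, where chance gives about 1 in 20, and no array was left out for it.

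Signals lay outside the comparisons of named genes. In the reference channel, 7 genes were well above background on all 4 LPS arrays and on no other array (Cxcl9, Il1a, Il1f6, Lipg, Mmp14, Serpina3f and Vgf), although all arrays should carry the same kind of reference. Of 22 genes as bright in red after LPS and dim in green elsewhere, these 7 were seen in green on all 4 LPS arrays and 4 on none. Their source was not tested. Among 4771 probes without a name here, limma called 998 after LPS, 75 at 200 µM, 10 at 50 µM, 11 between the doses, 1065 between 200 µM and LPS, and 1032 between 50 µM and LPS.

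Where the arrays are taken as unpaired, the 8 arrays of each comparison were split into 4 and 4 in every way. In each comparison 1 of 35 splits, the real one, called as many genes, the smallest share that 35 splits allow. A split that mixes the groups moves the treatment effect into the spread, so any large effect fixes its low count in advance. The gap between the counts is therefore no further evidence against chance. The real count and the highest other were 3924 and 21 for LPS, 383 and 0 at 200 µM, 47 and 0 at 50 µM, 3872 and 29 for 200 µM against LPS, and 3912 and 25 for 50 µM against LPS. Between the doses they were 104 and 7, where the 7 came from the split by scan day. With scan day as a block the doses differed in 120 genes, and on each day alone in 105 and 129. Where the letters pair the arrays, which may hold for LPS against control too, only 8 splits part all pairs as the real one does. These are too few for a share under 0.05, so chance is not excluded there. Beside the real counts above, the highest other among these was 21 for LPS against control and 0 at 200 µM, at 50 µM and between the doses. It was 29 for 200 µM against LPS and 25 for 50 µM against LPS.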

How the results depend on the processing

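Each scan day alone was the alternative chosen after seeing the data. Of 497 called results of named genes, 355 kept direction and call under every processing alternative and 3 reversed. With each replicate or single array left out in turn 443 always kept them, and 439 did on both scan days. Of 69 called list results 38, 62 and 62 did so and 0 reversed.

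Normexp correction lowered the counts to 151 (110 higher, 41 lower) at 200 µM, 19 (15 and 4) at 50 µM and 31 (22 and 9) between the doses. Without background subtraction they were 228 (170 and 58) at 200 µM and 28 (23 and 5) at 50 µM. Normexp adds an offset of 50 to each channel and the other keeps the background, and either can pull ratios of dim spots toward 0. Whether the lost calls are those of dim spots was not tested. Log ratios against 0, without the controls' spread, called 95 genes at 50 µM (77 and 18) and gave correlations with LPS of 0.256 at 200 µM and 0.165 at 50 µM. No filter gave a correlation of 0.136 at 50 µM, and the second scan day alone 0.138. The strict filter, which tests fewer genes (10966), left 68 between the doses (51 and 17), and single probes (21458 tested) gave 6012 for LPS, 6056 for 200 µM against LPS and 6015 for 50 µM against LPS. An adjusted p alone, with no minimum change, called 10056 after LPS, 2906 at 200 µM, 449 at 50 µM, 971 between the doses, 10117 for 200 µM and 10104 for 50 µM against LPS. Treat against 1.5-fold called 10 at 50 µM (9 and 1) and 33 between the doses (24 and 9). With an estimated correlation camera called 6 lists for LPS, 6 for 200 µM against LPS and 6 for 50 µM against LPS, and fry, which does not compare a list with other genes, called 27, 24 and 27. For the correlations the cause was not tested. Over genes called in either comparison they were 0.244 and 0.117, and with separate controls for heme and LPS 0.195 to 0.211 and 0.0585 to 0.0871.

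Reversed values were Spic at 200 µM against LPS with normexp (−1.08), Pdgfrb at 50 µM against 0 (1.11), and, from the red channel alone, Actb after LPS (−0.336), at 200 µM against LPS (0.149) and at 50 µM against LPS (0.221). The cause was not tested. No scaling moved the median of all genes by over 0.1 log2 against the main one.

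With the replicate as a block, the counts were 3927 for LPS, 390 at 200 µM, 54 at 50 µM, 119 between the doses, 3877 for 200 µM and 3920 for 50 µM against LPS, and 3922, 382, 46, 104, 3870 and 3912 of the called genes stayed called in the same direction. Among named genes the block ended the call of Ifi213 at 50 µM (adjusted p = 0.083) and made calls for Cxcl1, Cxcl3 and Gfi1b at 50 µM and between the doses, it ended 1 list call (fibroblast markers at 200 µM, adjusted p = 0.07), and it changed no other call. Slide and replicate are the same block, and the deposited table gave the same values as the scanner files, so neither has values of its own.

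Leaving out arrays or replicates gave 3767 to 4064 genes for LPS, 327 to 387 at 200 µM, 35 to 47 at 50 µM, 78 to 118 between the doses, 3723 to 4027 for 200 µM and 3755 to 4040 for 50 µM against LPS. The correlations were 0.193 to 0.233 and 0.0822 to 0.127. A replicate left out ended 5 of 126 calls of named genes after LPS, 14 of 65 at 200 µM, 9 of 20 at 50 µM and 11 of 29 between the doses, and normexp 7, 26, 11 and 17. Signal over background limits genes dim in the controls: 273 calls after LPS, 27 at 200 µM and 2 at 50 µM have only a bound.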

Other observations

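The test on the first scan day alone and the choice of genes called in opposite directions came only after the results were seen. Heme-albumin at 200 µM changed genes outside the lists' main themes. The lectin receptor gene Clec10a, a marker of macrophages activated by interleukin-4, rose by 2.74 ± 0.143 (adjusted p = 7.8e-09), while Tgm2, another such marker, fell by 2.1 ± 0.105 (adjusted p = 5.2e-09), so the alternative activation list went both ways (2 of 14 higher and 2 lower, median −0.184, adjusted p = 0.84, with a positive test direction). In the glycolysis and hypoxia list 1 of 28 genes was called higher and 2 lower (median −0.0333, adjusted p = 0.67). The vascular growth factor gene Vegfa fell by 2.02 ± 0.135 (adjusted p = 7.3e-08) and Ankrd37 by 1.62 ± 0.0988 (adjusted p = 3.2e-08), whereas the glucose transporter gene Slc2a1 rose by 1.13 ± 0.0782, with 0.994 on the first scan day alone, under 2-fold. The death receptor gene Fas, a p53 target, rose by 1.6 ± 0.136 (adjusted p = 9.2e-07), the pore gene Panx1 by 1.64 ± 0.209 and Tfec, a relative of the lysosomal regulator TFEB, by 1.45 ± 0.105. The cell adhesion gene Esam, listed as an endothelial marker, rose by 3.53 ± 0.339 (adjusted p = 3.1e-06) while the other 6 measured endothelial markers were not called on their brightest probe. A second probe of Kdr, 1 of the 6, was called at −1.39.

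Heme at 200 µM raised and LPS lowered 20 genes, fewer than the 43.2 for independent lists. Among them were the sorting receptor gene Sort1 (1.63 and −3.58), the iron exporter Slc40a1 (4.19 and −2.36) and the cholesterol synthesis gene Sqle (1.55 and −1.66). Heme lowered and LPS raised 38 genes, against 17.5 for independent lists. These included Thbs1 (−4.31 and 2.19), the Fc receptor gene Fcgr1 (−1.58 and 3.14), Tnfsf8 (−1.81 and 2.93) and the monocyte chemokines Ccl7 (−2.3 and 5.22) and Ccl2 (−1.58 and 4.56). The calls of Ccl7 and Ccl2 at 200 µM ended without replicate b (−2.1 and −1.42).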
